A study of Mus musculus with 72 samples.

How the data were processed

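Messenger RNA from the brain cortex of 72 mice, F1 animals of the strains C57BL/6J and FvB/NJ, was measured with 1 sequencing library per mouse. Libraries were strand-specific and read as paired ends of 69 bases, per the labels' protocols. Reads were aligned to the mouse genome mm10 with STAR and counted per gene with HTSeq, and edgeR and limma are also named, per the submitters' processing notes. The deposited values are RPKM, made by the authors from the reads assigned to each gene, divided by the length of the gene model and by the total of assigned reads of the library, scaled to 1 M reads. That no further scaling was applied between libraries was read from the values, as was the unit. In each library the values of a gene are whole multiples of the value of 1 read, so whole reads were recovered for 20323 genes, within a tolerance of 0.05 reads for 100% of the values above 0. A further 3737 of the 24060 genes listed were at 0 in every library, and 2 gene names were listed more than once. The recovered reads came to 13.1 to 22 M per library, which is the depth of every comparison. No pair of libraries was identical.

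Samples were grouped by the genotype and age in the labels into 12 groups of 6 mice, 3 females and 3 males each. Xist and Ddx3y were checked against the labelled sex, with 0 of 72 libraries mismatched. Counted within an age, the sample names held 39 first numbers, and 54 libraries shared theirs with another library. The meaning of the number was not stated. The mean residual correlation was 0.006 over the 34 pairs from different groups that share a number. It was 0 over the 614 other pairs from different groups of the same age. Pairs within a group were left out, among them the BAC-TREM2 libraries of 7 months with a low block on chromosome 11. The number entered as a block in 1 alternative only, with a consensus correlation of 0.174.

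A gene was tested if it reached 0.3 RPKM in at least 6 libraries, which left 15363 genes. Values were log2 of RPKM plus a pseudocount of 0.1, and limma (3.58.1, R 4.3.3, statmod 1.5.0) was fitted with the 12 groups and sex as terms and a robust empirical Bayes trend. All tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg within a comparison, with 0.05 as the threshold. Sex differences in the 5xFAD effect came from a model with the groups parted by sex. A quasi-likelihood test on read counts had been planned before the data were examined, and limma on log2 values took its place as the test for values deposited as RPKM; no quasi-likelihood test was run on the recovered reads, which were used for voom. Errors of log2 fold changes are standard errors of the fit, and errors of RPKM levels and list means are SD over 6 libraries unless another n is given. The fit holds 1 spread per gene over all groups. A standard error and its p-value may therefore be too small where the compared groups vary more than the others. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

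The lists, comparisons and alternatives were fixed before the data were examined, except where a choice is said to have been made after. The 31 gene lists covered homeostatic, early and late disease-associated and pan-microglial genes, complement and Fc receptors, MHC class I and II, interferon response, cytokines and chemokines, lysosome, cholesterol synthesis, lipid transport, reactive and other astrocyte genes, oligodendrocytes and their precursors, excitatory and inhibitory neurons, synapse, immediate early genes, endothelial and pericyte, fibroblast and meninges, red blood cell, choroid plexus, striatum, thalamus, hippocampus, leukocytes and border macrophages, proliferation, heat shock and mitochondrially encoded genes. Of these 29 could be tested: 0 of 7 red blood cell genes passed the filter and 0 of 13 mitochondrially encoded genes were in the files. Camera with a preset correlation of 0.01 was the main list test and was repeated with an estimated correlation, with adjustment over the lists within each of 12 comparisons. Fry, a further list test planned beside camera, was also run, and its results are not reported here. Some genes belong to more than 1 list, and 9 of 10 striatum, 8 of 8 thalamus, 7 of 8 hippocampus and 6 of 10 choroid plexus markers passed the filter in these cortex libraries.

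Genes are named by a rule. For each pair of groups at 1 age they are the 8 largest positive and 8 largest negative fold changes among called genes with a mean of at least 1 log2 CPM, computed here from the recovered reads, and the same sign in both sexes. Added to these are 20 fixed genes in every comparison (among them Trem2, App, Thy1, Apoe, Tyrobp, Cst7, Clec7a, Itgax, Spp1, Gpnmb, Lpl, C4b, Gfap, Serpina3n, P2ry12, Tmem119, Cx3cr1, C1qa and Cd74), the 2 to 4 members of a described list with the smallest p, and the 4 largest per direction for interaction, age and sex differences. Unnamed gene models were skipped, and some genes that the rule selects are not reported here. Coordinates are from GENCODE vM21, on the same assembly as mm10, in which 14647 of the 15363 tested genes (95.3%) were matched by name.

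Alternatives were median-of-ratios size factors, no filter on low values, a mean of at least 1 CPM, limma voom on the recovered reads with and without the block, the 24 libraries of an age alone and no sex term. Chosen after the data were seen were pseudocounts of 0.01 and 1, 2 residual principal components as covariates, the 12 libraries of the compared groups alone, leaving out both libraries with a low block on chromosome 11, leaving out each library in turn for the main comparisons at 4 and 7 months, and pooling BAC-TREM2 against WT over the ages. Going from totals to size factors rescaled libraries by 0.968 to 1.03 and moved the median of all genes by at most 0.0333 on the log2 scale in any comparison.

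The fit was tested on simulated data for 5xFAD against WT at 7 months, with 15262 genes and 200 changed ones, 50 for each fold size. It called 68% of genes changed 1.25-fold, 88% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 2 false calls among 178. The simulated spread came from the WT libraries, the changed genes had a mean of at least 1 CPM, and genes were drawn independently. Real 5xFAD libraries often vary more than WT, so these rates may be too favourable for them. For each comparison 100 splits of its samples into groups of the same sizes, the real one included, were refitted. Each library was scanned for runs of 10 neighbouring genes whose median log2 deviation passed 0.5, over 11339 genes at 1 RPKM or more.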

Results

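Poly(A) RNA from the cortex of 72 mice was sequenced, with 1 library per mouse, in 4 genotypes at 3 ages. Wild-type (WT) mice were set beside mice with BAC-TREM2, a bacterial artificial chromosome that holds the human TREM2 gene, and beside 5xFAD mice, which carry human transgenes, APP among them, with familial Alzheimer's disease mutations. A further genotype, 5xFAD/BAC-TREM2, carried both. TREM2 is a lipid-sensing receptor of microglia, the resident phagocytes of the brain. Each genotype was sampled at 2, 4 and 7 months, which made 12 groups of 6 libraries, 3 from females and 3 from males. The reads recovered from the deposited RPKM values came to between 13.1 and 22 M per library, with a median of 18.3 M, and 15363 genes passed the filter on low values.

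The 5xFAD transgenes were visible in the mouse genes that they resemble. Thy1, whose regulatory sequence drives the transgenes, lay between 1000 and 1470 RPKM in the 36 carriers of 5xFAD and between 517 and 631 RPKM in the 36 other mice. App was above every other mouse in 33 of the 36 carriers. Mouse Trem2 (chromosome 17, 48346401 to 48354147, mm10) did not pass the test between BAC-TREM2 and WT, with log2 fold changes of 0.22 ± 0.17, -0.07 ± 0.17 and -0.02 ± 0.17 (SE, n = 6 per group) at 2, 4 and 7 months. Mouse Trem2 therefore gave no check on which mice carried BAC-TREM2. Reads were aligned to the mouse genome, so Trem2 below means the mouse gene, and RNA of the human TREM2 gene was not measured as such. Sex-linked genes matched the labelled sex in the 72 libraries.

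At 2 months the cortex of 5xFAD mice differed from WT in 4 genes, Thy1, App and Mme among them. Thy1 rose to 1120 ± 70 RPKM from 568 ± 12 (SD, n = 6 per group) and App to 738 ± 30 from 624 ± 15. Mme (chromosome 3, 63241537 to 63386030, mm10) encodes neprilysin, a peptidase that degrades amyloid beta. It fell by 0.65 ± 0.13 on the log2 scale (SE, adjusted p = 0.024), to 0.901 ± 0.14 RPKM from 1.46 ± 0.11, and the 6 carriers lay below the 6 WT mice. None of the microglial or astrocyte genes named in advance passed the test at this age, with Trem2 at a log2 fold change of 0.24 ± 0.17 and Gfap at 0.19 ± 0.23.

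Of the gene lists, the cholesterol synthesis enzymes and the interferon response had the smallest camera p among those higher in 5xFAD mice at 2 months, each by small values per gene. The 17 cholesterol synthesis genes had positive log2 fold changes with a median of 0.15, among them Fdft1 at 0.22 ± 0.07 and Srebf2 at 0.11 ± 0.04. For interferon response genes the median was 0.24, and 21 of 22 were positive, with Ifit3 at 0.73 ± 0.20 and Ifit1 at 0.56 ± 0.23. No member of either list passed the test over all genes, while 4 cholesterol genes and 1 interferon gene did when adjusted over the list alone. Camera gave adjusted p = 1.4e-13 and 3.3e-08 with its preset correlation, and adjusted p = 0.092 for each list with an estimated correlation. The leukocyte and border macrophage list, with a median of 0.36 over 4 genes, was also higher and the oligodendrocyte list lower (adjusted p = 0.013 and 0.022), at adjusted p = 0.092 and 0.9 with an estimated correlation. At 2 months 577 genes had an unadjusted p under 0.05, against 768 that chance gives. The call on Mme ended in a fit of the 12 libraries alone (adjusted p = 0.23).

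At 4 months 5xFAD mice showed a large rise of microglial genes. Cst7 (chromosome 2, 150570415 to 150578944, mm10), which encodes cystatin F, an inhibitor of cathepsins, rose to 17.1 ± 11 RPKM from 0.0655 ± 0.065 in WT (SD, n = 6 per group), a log2 fold change of 6.55 ± 0.37 (SE) whose size depends on the pseudocount because WT lay near 0. Itgax, the integrin CD11c, rose by 3.45 ± 0.28, Clec7a, the receptor dectin-1, by 3.25 ± 0.34, and the chemokine gene Ccl6 by 3.11 ± 0.22. Trem2 rose to 22.1 ± 9.1 RPKM from 7.44 ± 0.69 and its signalling adaptor Tyrobp to 47.2 ± 23 from 14.3 ± 0.89, each above every WT mouse in 6 of 6. Lyz2, Mpeg1, Cd68 and Slc15a3, genes of phagocytes and their lysosomes, rose by 1.43 ± 0.21, 1.33 ± 0.15, 1.31 ± 0.15 and 1.29 ± 0.20. Gfap, the intermediate filament of astrocytes, rose to 83.9 ± 34 RPKM from 32.7 ± 4, and C4b, a complement gene that the reads may not separate from its near-identical neighbour C4a, rose by 1.02 ± 0.21.

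Among the genes named by the rule, those that fell at 4 months did so by much smaller amounts. A further called gene, which the rule left out, fell by more than 1 on the log2 scale. Mme fell by 0.73 ± 0.13 on the log2 scale, and Gmps, which encodes an enzyme of purine synthesis and lies near Mme on chromosome 3, fell by 0.35 ± 0.06. The other named decreases were in Plcxd3, Pcdha11, Npsr1, Gprin3, Kcnh7 and Clcn5, with log2 fold changes from -0.42 to -0.34, of which Npsr1 encodes the receptor for neuropeptide S and Kcnh7 a potassium channel. Pcdha11 shares exons with its neighbours in the protocadherin cluster, so its value may hold their reads. Leaving out 1 of the 12 libraries ended the call on Plcxd3 in 3 fits, on Clcn5, Gprin3 and Kcnh7 in 8 fits each and on Pcdha11 in 10, and the highest adjusted p were 0.076 and 0.14 for Plcxd3 and Kcnh7 without WT replicate 1, 0.11 for Clcn5 without 5xFAD replicate 4, 0.15 for Gprin3 without 5xFAD replicate 5 and 0.17 for Pcdha11 without 5xFAD replicate 3. Spp1, Gpnmb, Lpl, Serpina3n, P2ry12 and Cd74 did not pass the test at this age, with Spp1 at 0.65 ± 0.24 (adjusted p = 0.09) and Cd74 at 0.76 ± 0.27 (adjusted p = 0.068).

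The microglial lists were higher at 4 months, the pan-microglial one in nearly every member. Of 16 pan-microglial and myeloid genes 15 rose (16 adjusted over the list alone), with Ly86 at 1.13 ± 0.15 and the protease gene Ctss at 0.86 ± 0.12. Among homeostatic microglial genes 12 of 16 rose (14 over the list alone), with Selplg at 0.47 ± 0.08 and Csf1r, the receptor that microglia need to survive, at 0.48 ± 0.09. The early disease-associated microglia list had 7 of 10 genes higher (9 over the list alone), and the late one 13 of 21 (17 over the list alone). Lysosomal genes rose in 18 of 26 (23 over the list alone), among them Ctsd at 0.91 ± 0.10, complement and Fc receptor genes in 9 of 13 (10 over the list alone), among them Fcer1g at 0.87 ± 0.12, and cytokine and chemokine genes in 3 of 12 (6 over the list alone), among them Ccl3 at 3.45 ± 0.33. These 7 lists passed camera with the preset correlation and with an estimated one, where the highest adjusted p was 0.0091. Inhibitory neuron and synapse genes were lower as lists (adjusted p = 0.0075 and 0.014 with an estimated correlation), although Gad1, the enzyme that makes GABA, at -0.14 ± 0.04 was the 1 member called, and the synapse list had none; over each list alone the counts were 2 and 0.

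A further 9 lists passed at 4 months with the preset correlation alone. Of cholesterol synthesis genes 6 of 17 rose (14 adjusted over the list alone), with Mvd at 0.51 ± 0.10 and Fdft1 at 0.30 ± 0.07, and camera gave adjusted p = 0.14 with an estimated correlation. Lipid transport and storage genes rose in 4 of 15 (5 over the list alone; adjusted p = 0.11 with an estimated correlation), with Npc2 at 0.39 ± 0.07 and Ch25h, which makes 25-hydroxycholesterol, at 1.63 ± 0.30. In the reactive astrocyte list 3 of 21 rose (7 over the list alone; adjusted p = 0.23 with an estimated correlation), and in the astrocyte list 3 of 16 (4 over the list alone; adjusted p = 0.39 with an estimated correlation). MHC class I, MHC class II and the interferon response had 1 of 10, 1 of 6 and 3 of 22 members higher (7, 4 and 5 over the list alone), at adjusted p = 0.15, 0.18 and 0.39 with an estimated correlation. Oligodendrocyte and excitatory neuron genes had 1 of 15 and 1 of 12 lower (1 and 1 over the list alone), at adjusted p = 0.52 and 0.15 with an estimated correlation. Choroid plexus markers, from a tissue that borders the cortex, averaged -0.09 ± 1.55 log2 RPKM in 5xFAD mice and -0.87 ± 0.35 in WT (SD, n = 6 per group) and did not pass as a list (adjusted p = 0.13).

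By limma, 758 genes were higher and 251 lower in 5xFAD mice at 4 months, 54 and 1 of them by more than a log2 fold change of 1. With median-of-ratios size factors the split was 551 higher and 610 lower, and with the 12 libraries of both groups alone 231 and 25. The count was 508, 645 and 571 without WT replicates 1, 2 and 4, 517, 468 and 495 without 5xFAD replicates 3, 4 and 5, and 1675 without 5xFAD replicate 2. Tmem119 and Apoe were called at 0.26 ± 0.08 and 0.25 ± 0.06, and without 5xFAD replicate 4 both calls ended (adjusted p = 0.18 and 0.063). The call on Tmem119 ended in 9 of the 12 fits without 1 library.

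**Figure D1:**
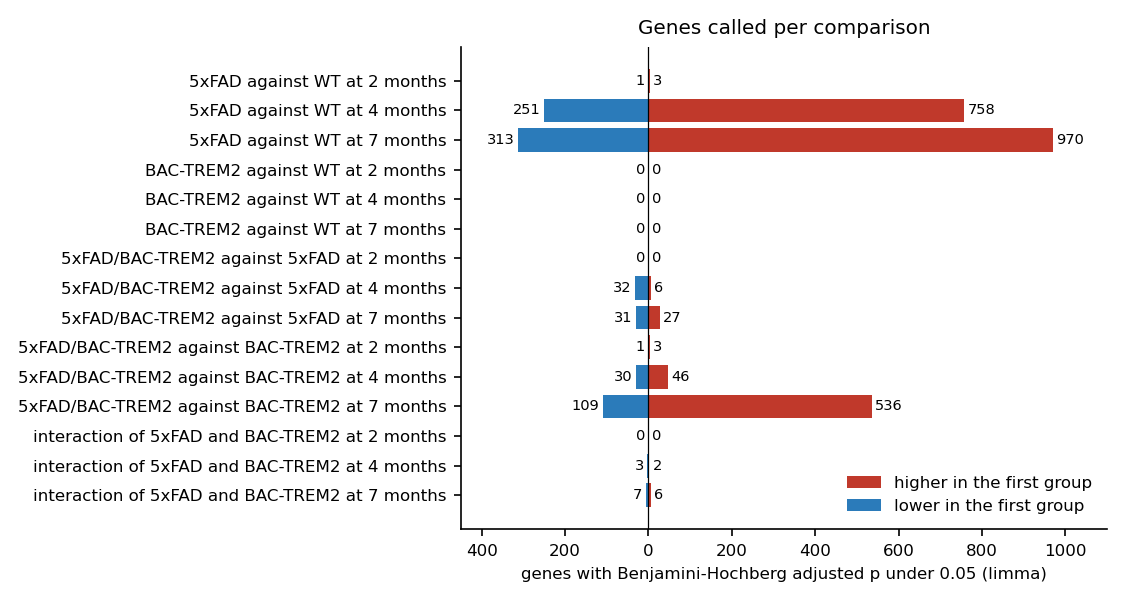
Number of genes called by limma at an adjusted p under 0.05 in each comparison (horizontal axis, genes), with genes higher in the first-named group to the right of 0 and lower to the left. The 5xFAD comparison with WT went from 3 higher and 1 lower at 2 months to 970 higher and 313 lower at 7 months, and BAC-TREM2 against WT had 0 at each age.

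At 7 months 5xFAD mice again had higher levels of these glial genes than WT, while in the test between 4 and 7 months the 5xFAD effect differed in 1 gene, Gpnmb. Cst7 was at 49.1 ± 18 RPKM in 5xFAD mice against 0.122 ± 0.097 in WT (SD, n = 6 per group), and Itgax, Clec7a and Ccl6 rose by 4.79 ± 0.28, 4.69 ± 0.34 and 3.69 ± 0.22 on the log2 scale (SE). Trem2 rose to 41.4 ± 15 RPKM from 8.82 ± 1.4 and Tyrobp to 88.7 ± 35 from 15.6 ± 2.2. Spp1 (chromosome 5, 104435118 to 104441050, mm10), which encodes the secreted protein osteopontin, and Gpnmb, a glycoprotein of lipid-laden phagocytes, passed the test, at 10.4 ± 3.6 RPKM against 2.64 ± 0.51 and 3.24 ± 1.1 RPKM against 0.548 ± 0.15. Lyz2, a gene with the close relative Lyz1, rose by 2.76 ± 0.21, Slc11a1, a metal transporter of phagosomes, by 2.33 ± 0.22, and C4b by 2.21 ± 0.21. Gfap was at 231 ± 140 RPKM against 35.4 ± 2.9, and a further astrocyte gene, Serpina3n, rose by 0.99 ± 0.15. Apoe rose by 0.39 ± 0.06, Lpl by 0.84 ± 0.10, Cd74 by 1.41 ± 0.27, C1qa by 1.48 ± 0.12, and the homeostatic genes Cx3cr1, P2ry12 and Tmem119 by 0.75 ± 0.08, 0.58 ± 0.10 and 0.40 ± 0.08.

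Among the genes that fell at 7 months was Cort, which encodes cortistatin, a neuropeptide of inhibitory neurons. Its level was 12.3 ± 4.5 RPKM in 5xFAD mice and 21.8 ± 4.9 in WT (SD, n = 6 per group), and it fell by 0.88 ± 0.17 on the log2 scale (SE). Mme fell by 0.80 ± 0.13, Tcap by 0.73 ± 0.17, Lgr5 by 0.66 ± 0.16 and the neuronal GTPase gene Rem2 by 0.65 ± 0.18. Frzb, Cartpt and Ankrd63 fell by 0.62 ± 0.17, 0.60 ± 0.19 and 0.51 ± 0.15. Without 5xFAD replicate 1 the calls on Rem2, Frzb, Cartpt and Ankrd63 ended, at adjusted p = 0.1, 0.11, 0.26 and 0.24, and 3, 2, 6 and 4 of the 12 fits without 1 library ended them. A fit of the 12 libraries alone ended the calls at 7 months on Cort, Tcap, Lgr5, Rem2, Frzb, Cartpt and Ankrd63, at adjusted p = 0.12, 0.086, 0.12, 0.14, 0.38, 0.44 and 0.44, and on Serpina3n and Cd74, at 0.13 and 0.065.

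Every one of the 16 pan-microglial genes rose at 7 months, with a median log2 fold change of 1.36, and Ly86 at 1.92 ± 0.15 and Laptm5 at 1.37 ± 0.10 had the smallest p. Lysosomal genes rose in 25 of 26, among them Ctsd at 1.52 ± 0.10 and Cd68 at 1.96 ± 0.15. Homeostatic genes rose in 15 of 16, the early and late disease-associated lists in 8 of 10 and 17 of 21, complement and Fc receptors in 12 of 13, and cytokines and chemokines in 5 of 12. MHC class I genes rose in 9 of 10, among them B2m at 0.83 ± 0.09, MHC class II genes in 4 of 6, among them H2-Ab1 at 1.42 ± 0.26, and interferon response genes in 10 of 22, among them Bst2 at 1.12 ± 0.21. Reactive astrocyte genes rose in 10 of 21, with Osmr at 1.16 ± 0.14 and Aspg at 1.68 ± 0.20, and lipid transport genes in 10 of 15, with Ch25h at 2.75 ± 0.30. Proliferation genes rose in 3 of 6, with the mitotic genes Ccna2 at 0.86 ± 0.21 and Top2a at 1.13 ± 0.27. Adjusted over the list alone, these 13 lists in the order given had 16, 25, 15, 9, 18, 12, 8, 10, 6, 15, 14, 11 and 3 members higher, and 1 lipid transport gene lower. Each passed camera with the preset and with an estimated correlation, with the highest adjusted p at 0.041 for proliferation.

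Neuronal genes moved the other way at 7 months. Inhibitory neuron genes fell in 5 of 12 (6 adjusted over the list alone), with Gad1 at -0.22 ± 0.04, the neuregulin receptor gene Erbb4 at -0.36 ± 0.07, Slc32a1, the vesicular GABA transporter, at -0.20 ± 0.04, and Pvalb at -0.30 ± 0.08. Synapse genes fell in 6 of 20 (7 over the list alone), with Rab3a at -0.15 ± 0.03 and Syt1, the calcium sensor of transmitter release, at -0.18 ± 0.04. Both lists passed with an estimated correlation (adjusted p = 9.4e-05 and 0.0027). Excitatory neuron genes fell in 3 of 12 (3 over the list alone; adjusted p = 0.063 with an estimated correlation), among them Tbr1 at -0.21 ± 0.05 and Fezf2 at -0.28 ± 0.07. The immediate early genes were lower as a list at the preset correlation with no member called (adjusted p = 0.54 with an estimated correlation). Astrocyte genes rose in 7 of 16 (8 over the list alone; adjusted p = 0.056 with an estimated correlation), among them the water channel gene Aqp4 at 0.64 ± 0.09. Cholesterol synthesis genes rose in 6 of 17 (15 over the list alone; adjusted p = 0.13 with an estimated correlation) and endothelial and pericyte genes in 3 of 15 (6 over the list alone; adjusted p = 0.18 with an estimated correlation). Choroid plexus markers averaged -0.11 ± 1.28 log2 RPKM in 5xFAD mice and -0.78 ± 0.20 in WT.

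In all, 970 genes were higher and 313 lower in 5xFAD mice at 7 months, and 154 and 0 passed a log2 fold change of 1. With median-of-ratios size factors the split was 820 higher and 565 lower, and with the 12 libraries of both groups alone 560 and 41. Without 5xFAD replicate 1 the count was 835.

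How the 5xFAD effect changed with age was tested as a difference of differences. From 2 to 4 months the effect on 126 genes became larger in the positive direction, among them Ccl6 (2.53 ± 0.31 log2, SE), Tyrobp (1.48 ± 0.25), Cd68 (1.42 ± 0.21) and Lyz2 (1.37 ± 0.30). It became more negative for 6, among them the neuronal genes Pcdhac2 (-0.27 ± 0.07) and Myt1l (-0.26 ± 0.06), and Ttc3 and Prmt5 (both -0.17 ± 0.04). Between 2 and 7 months 410 genes moved up, with Ccl6 at 3.11 ± 0.31, Lyz2 at 2.70 ± 0.30, Tyrobp at 2.34 ± 0.25 and Gfap at 2.31 ± 0.32. Another 32 moved down, with Asic4, an ion channel gene, at -0.55 ± 0.15, Lgi2 at -0.41 ± 0.12, and Zfp536 and Zfp30 at -0.40 ± 0.12 and -0.40 ± 0.10. From 4 to 7 months 1 gene passed, Gpnmb, whose 5xFAD effect grew by 1.92 ± 0.25 (adjusted p = 1.7e-06). With median-of-ratios size factors the counts were 82 up and 20 down from 2 to 4 months and 365 up and 76 down from 2 to 7 months. With voom 3 genes passed from 4 to 7 months, and voom ended the calls from 2 to 4 months on Lyz2 and Prmt5 (adjusted p = 0.062 and 0.057).

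Whether the 5xFAD effect differed between females and males was tested gene by gene, and no list was tested for it. At 4 months the 5xFAD effect was larger in females for 22 genes and smaller for 0. Sex was partly confounded there with the share of reads on Rn45s, which no fit held as a term. In 5xFAD mice it was 0.19%, 0.21% and 0.22% in males and 0.25%, 0.29% and 0.24% in females. In WT it was 0.19%, 0.2% and 0.24% in males and 0.2%, 0.27% and 0.28% in females. Tyrobp averaged 65.6 ± 16 RPKM in 5xFAD females and 28.8 ± 6.6 in 5xFAD males (SD, n = 3 per sex), against 13.9 and 14.7 in WT females and males. Slc11a1, Rac2, a GTPase of leukocytes, and Cd68 had differences of 1.69 ± 0.33, 1.24 ± 0.23 and 1.13 ± 0.19 on the log2 scale (SE). At 7 months 3 genes passed, Mpeg1 (0.95 ± 0.16), the integrin gene Itgb5 (0.70 ± 0.14) and the cathepsin gene Ctsd (0.69 ± 0.12), with Ctsd at 631 ± 96 RPKM in 5xFAD females and 378 ± 27 in males. At 2 months the 1 gene called was Gm16740, an unannotated gene model chosen here after its values were seen. The 24 libraries of each age gave 0 calls at 2, 4 and 7 months, where limma had given 1, 22 and 3, and voom gave 0 at 2 months and 12 at 4 months. Leaving out 1 library gave 37, 13, 14 and 13 genes at 4 months without WT replicates 1, 3, 4 and 6 and 40, 5, 40 and 4 without 5xFAD replicates 1, 2, 3 and 4, and at 7 months 5, 0 and 29 without 5xFAD replicates 3, 4 and 5. Without 5xFAD replicate 4 the calls on Tyrobp, Slc11a1 and Rac2 at 4 months (adjusted p = 0.081, 0.081 and 0.064) and on Ctsd, Mpeg1 and Itgb5 at 7 months (adjusted p = 0.085, 0.088 and 0.6) ended. Those on Tyrobp, Slc11a1 and Rac2 also ended without 5xFAD replicate 2 of 4 months, and that on Itgb5 ended in 7 of the 12 fits without 1 library.

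BAC-TREM2 alone left no gene past the test at any age. Among the 20 genes named in advance the larger values were in Itgax, with log2 fold changes of 0.90, 1.13 and 0.87 (each ± 0.28, SE, n = 6 per group) at 2, 4 and 7 months, in Spp1, with 0.76, 0.88 and 0.67 (each ± 0.24), and at 4 months in Cst7, with 1.15 ± 0.37. Itgax lay at 0.211, 0.236 and 0.201 RPKM in BAC-TREM2 mice and at 0.0631, 0.0459 and 0.0502 RPKM in WT. Tyrobp, C1qa, Gfap and P2ry12 changed by at most 0.33 in either direction. Limma called 0 genes at 2, 4 and 7 months, with 935, 490 and 944 at an unadjusted p under 0.05 against 768 from chance, and voom called 0 at each age. Of the gene lists 9, 1 and 6 passed with the preset correlation. At 2 months 8 were higher, among them complement and Fc receptors, late disease-associated, pan-microglial and reactive astrocyte genes (medians 0.19, 0.05, 0.08 and 0.10; 0, 3, 1 and 0 members higher adjusted over the list alone and 0 over all genes; adjusted p = 0.54, 0.54, 0.76 and 0.54 with an estimated correlation), and 1, cholesterol synthesis, was lower. At 4 months the 1 list, fibroblast and meninges, was lower, and at 7 months 2 were higher and 4 lower, with the smallest p for lower oligodendrocyte genes. None of these passed with an estimated correlation, where cholesterol synthesis, fibroblast and oligodendrocyte genes had adjusted p = 0.54, 0.8 and 0.45, and each of these had 0 members called over all genes and 0 adjusted over the list alone. A fit of the 12 libraries or of the 24 libraries of 4 months, and a pseudocount of 0.01, each called 1 gene at 4 months. In 2 of the 6 BAC-TREM2 libraries of 7 months, replicates 4 and 5, 13 neighbouring genes on chromosome 11 had a median log2 deviation of -0.99 from the other libraries.

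**Figure D2:**
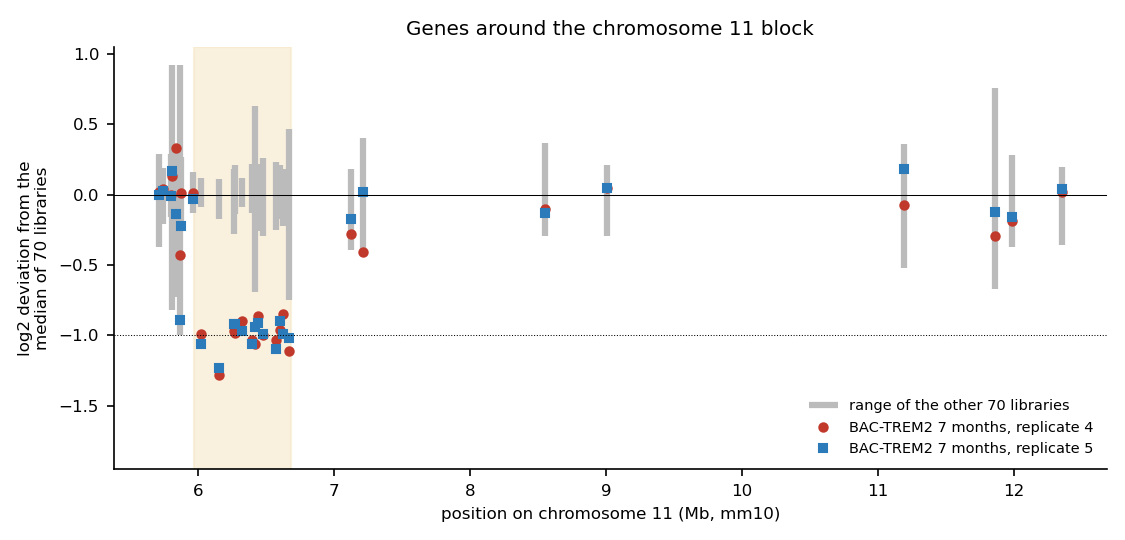
Log2 deviation of each gene from the median of 70 libraries (vertical axis) against position on chromosome 11 (horizontal axis, Mb, mm10), for genes at 1 RPKM or more. Points are BAC-TREM2 replicates 4 and 5 of 7 months, grey bars span the lowest to the highest of the other 70 libraries, and the shaded block of 13 genes from 5.97 to 6.68 Mb has a median of -0.99 in both.

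Adding BAC-TREM2 to 5xFAD changed no gene past the test at 2 months. Itgax and Spp1 again had the largest values among the genes named in advance, at 1.12 ± 0.28 and 0.88 ± 0.24 log2 (SE, n = 6 per group; adjusted p = 0.92 and 1). Trem2, Tyrobp and Gfap stood at -0.04 ± 0.17, 0.04 ± 0.18 and 0.14 ± 0.23. Limma and voom both called 0 genes, and 590 had an unadjusted p under 0.05 by limma. With the preset correlation 7 lists passed, 3 higher (late disease-associated, complement and Fc receptor, and excitatory neuron genes, with medians of 0.02, 0.16 and 0.04 and adjusted p = 0.58, 0.58 and 0.33 with an estimated correlation) and 4 lower, among them lower cholesterol synthesis (median -0.12) and a lower interferon response (median -0.19), both at adjusted p = 0.33 with an estimated correlation. No member of the 7 passed over all genes, and adjusted over the list alone 2 late disease-associated genes were higher, 3 cholesterol genes lower and 0 interferon genes. Insig1 stood at -0.24 ± 0.09, and Ifit3 at -0.45 ± 0.20 had the smallest p of the interferon genes.

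At 4 months the genes lower in 5xFAD/BAC-TREM2 than in 5xFAD included microglial genes that 5xFAD had raised, and the higher ones included Spp1 and Gpnmb, which had not passed in 5xFAD against WT. Cst7 fell to 0.811 ± 0.55 RPKM in 5xFAD/BAC-TREM2 from 17.1 ± 11 in 5xFAD (SD, n = 6 per group), a log2 fold change of -4.19 ± 0.37 (SE), where WT lay at 0.0655 ± 0.065. Tyrobp fell to 22.5 ± 5.3 RPKM from 47.2 ± 23, mouse Trem2 to 11.6 ± 2.3 from 22.1 ± 9.1, and Siglech, a lectin of resting microglia, to 4.07 ± 0.36 from 6.47 ± 1.7, with 6 of 6 mice below every 5xFAD mouse for Siglech. Clec7a, Ccl6, Mpeg1, Cd68, Ctsd and Csf3r fell by 1.51 ± 0.34, 1.16 ± 0.22, 0.79 ± 0.15, 0.63 ± 0.15, 0.58 ± 0.10 and 0.57 ± 0.14. Spp1 moved in the opposite direction, to 24.1 ± 14 RPKM from 3.44 ± 0.64, above every 5xFAD mouse in 6 of 6, and Gpnmb rose to 1.54 ± 0.70 RPKM from 0.741 ± 0.23. Hs3st4, Pfkp and Eef1a2, genes expressed in neurons, were higher by 0.20 ± 0.05, 0.15 ± 0.03 and 0.10 ± 0.02. Gfap, C4b, C1qa and Itgax did not pass, at -0.08 ± 0.23, 0.07 ± 0.21, -0.29 ± 0.12 and -0.29 ± 0.28.

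Homeostatic microglial genes were the 1 list lower at 4 months with both correlations. Its 16 members had a median of -0.27, 5 passed the test and 12 did when adjusted over the list alone, with Siglech at -0.62 ± 0.11 and Selplg at -0.41 ± 0.08 (adjusted p = 0.011 with an estimated correlation). Lysosomal genes fell in 6 of 26 (13 over the list alone), with Gusb at -0.51 ± 0.10, and pan-microglial genes in 2 of 16 (10 over the list alone), with Ctss at -0.56 ± 0.12, both at adjusted p = 0.11 with an estimated correlation. The late disease-associated list had 2 members higher, Spp1 and Gpnmb, and 5 lower (2 and 10 over the list alone), at adjusted p = 0.11 with an estimated correlation. In all 17 lists passed with the preset correlation, 4 higher and 13 lower. Among them, immediate early genes, which report recent neuronal activity, had a median of -0.83, with 0 members called and 11 lower over the list alone (adjusted p = 0.16 with an estimated correlation). Choroid plexus markers were lower too, with a median of -0.53 and 0 members called (1 lower over the list alone; adjusted p = 0.25 with an estimated correlation), and averaged -0.95 ± 0.25 log2 RPKM in 5xFAD/BAC-TREM2 against -0.09 ± 1.55 in 5xFAD.

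Limma called 6 genes higher and 32 lower in 5xFAD/BAC-TREM2 against 5xFAD at 4 months. Reads on Rn45s made up 0.19% and 0.21% in 5xFAD replicates 1 and 2 and at least 0.22% in every 5xFAD/BAC-TREM2 library of that age. No fit held this share as a term. With the 24 libraries of 4 months alone 2 calls were left, while Tyrobp, Trem2, Siglech, Ctsd and Gpnmb had adjusted p = 0.078, 0.059, 0.059, 0.059 and 0.078 and the 12 libraries of both groups gave 10 calls. Leaving out 1 library gave 23, 19, 15, 22 and 64 genes without 5xFAD replicates 1, 3, 4, 5 and 6 and 18, 16 and 22 without 5xFAD/BAC-TREM2 replicates 3, 4 and 5, and the calls on Trem2 and Mpeg1 ended without 5xFAD replicate 4 (adjusted p = 0.056 and 0.05). The calls on Cst7 and Spp1 held in each fit tried. Clec7a, Cd68, Csf3r, Hs3st4, Pfkp and Eef1a2 lost their calls in 8, 8, 8, 6, 7 and 6 of the 12 fits without 1 library, with the highest adjusted p at 0.16, 0.24, 0.25, 0.16, 0.2 and 0.16.

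**Figure D3:**
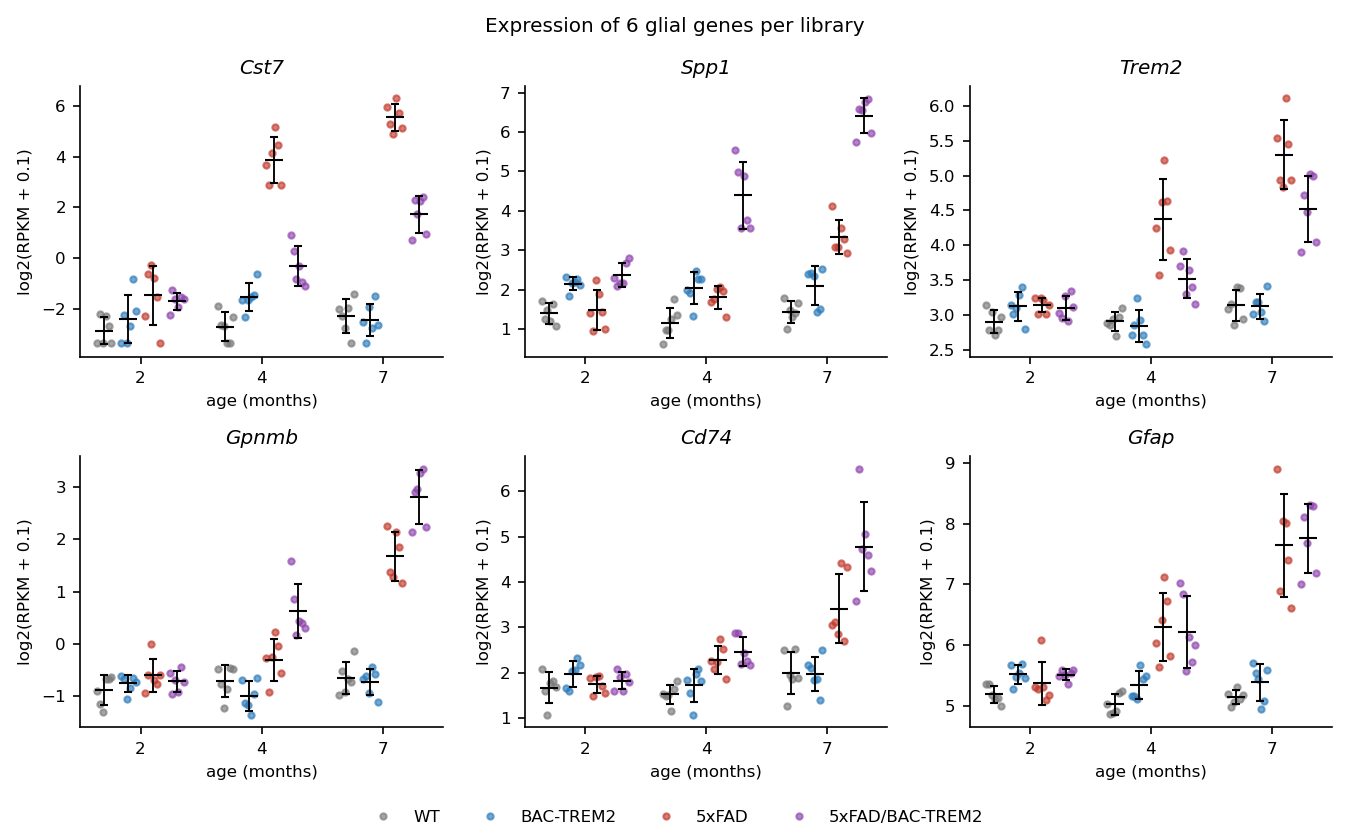
Log2 of RPKM plus 0.1 (vertical axes) in each library for Cst7, Spp1, Trem2, Gpnmb, Cd74 and Gfap, by age in months and genotype. Points are libraries, 6 per group, with the mean ± SD as black bars, and at 7 months Cst7 and mouse Trem2 were lower and Spp1, Gpnmb and Cd74 higher in 5xFAD/BAC-TREM2 than in 5xFAD, with Gfap at 230 ± 83 against 231 ± 140 RPKM.

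At 7 months BAC-TREM2 raised some genes in 5xFAD mice and lowered others. Spp1 rose to 87.9 ± 25 RPKM from 10.4 ± 3.6 (SD, n = 6 per group), a log2 fold change of 3.07 ± 0.24 (SE), and Gpnmb to 7.28 ± 2.4 from 3.24 ± 1.1. The antigen presentation genes Cd74 and H2-Ab1 rose to 34.1 ± 28 RPKM from 11.9 ± 6.8 and to 12.1 ± 9 from 3.87 ± 1.9, each above every 5xFAD mouse in 4 of 6. Lag3, Clec5a, Rassf4 and Zfp536 rose by 1.06 ± 0.17, 0.78 ± 0.17, 0.42 ± 0.10 and 0.39 ± 0.08. Cst7 fell to 3.53 ± 1.6 RPKM from 49.1 ± 18, Tyrobp to 45.8 ± 16 from 88.7 ± 35, mouse Trem2 to 24 ± 7.4 from 41.4 ± 15 and the cathepsin gene Ctsd to 313 ± 67 from 504 ± 150. Siglech fell by 0.80 ± 0.11, and Ly6g6e, Abi3, Csf3r and Slc2a5, a fructose transporter of microglia, fell by 1.33 ± 0.32, 0.60 ± 0.14, 0.55 ± 0.14 and 0.55 ± 0.12. Gfap stood at 0.12 ± 0.23, C1qa at -0.05 ± 0.12, Apoe at 0.04 ± 0.06 and P2ry12 at -0.30 ± 0.10, and these did not pass. Atp6v0d2, a proton pump subunit, Postn and Lgals3, which encodes galectin-3, rose by 2.46 ± 0.24, 2.11 ± 0.18 and 2.27 ± 0.33, and Dcstamp fell by 2.32 ± 0.27; these 4 were chosen after their values were seen.

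MHC class II genes were the 1 list that rose with both correlations at 7 months, and homeostatic microglial genes again were lower. Of 6 MHC class II genes 4 rose, H2-Aa, H2-Ab1, H2-Eb1 and Cd74, by 1.71 ± 0.30, 1.49 ± 0.26, 1.45 ± 0.26 and 1.37 ± 0.27, and 4 also did adjusted over the list alone (adjusted p = 0.0017 with an estimated correlation). Homeostatic genes fell in 3 of 16, Siglech, Selplg and Slc2a5 (11 over the list alone; adjusted p = 0.029 with an estimated correlation). The preset correlation gave 9 lists in all. Lysosomal and pan-microglial genes were lower, with 1 of 26 and 1 of 16 called (9 and 5 over the list alone; adjusted p = 0.5 and 0.55 with an estimated correlation). Oligodendrocyte and synapse genes were higher with 0 members called (adjusted p = 0.5 and 0.18 with an estimated correlation). Endothelial, proliferation and choroid plexus genes were lower with 0 called (3, 1 and 0 over the list alone; adjusted p = 0.24, 0.25 and 0.55 with an estimated correlation). The choroid plexus markers averaged -0.92 ± 0.20 log2 RPKM in 5xFAD/BAC-TREM2 and -0.11 ± 1.28 in 5xFAD.

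Limma called 27 genes higher and 31 lower at 7 months, and 31 higher and 24 lower with median-of-ratios size factors. Voom called 44 higher and 55 lower, 99 in all, voom with the block 40 higher and 80 lower, and the 24 libraries of that age gave 25 genes. Without 5xFAD replicates 1, 2, 3 and 6 the count was 30, 101, 35 and 168, and without 5xFAD/BAC-TREM2 replicate 6 it was 30. With the 24 libraries alone the calls on Cd74, H2-Ab1, Trem2, Clec5a, Rassf4, Zfp536, Ly6g6e, Abi3 and Csf3r ended, at adjusted p = 0.22, 0.13, 0.098, 0.087, 0.14, 0.086, 0.3, 0.054 and 0.085. Leaving out 5xFAD replicate 4 ended the call on Trem2 (adjusted p = 0.063), and leaving out 5xFAD replicate 3 that on Clec5a (adjusted p = 0.074). The calls on Trem2, Abi3, Csf3r, Ly6g6e, Rassf4 and Zfp536 ended in 3, 5, 10, 6, 9 and 4 of the 12 fits without 1 library. The highest adjusted p of Abi3, Csf3r, Ly6g6e and Zfp536 were 0.2, 0.24, 0.34 and 0.079 without 5xFAD replicate 1, and that of Rassf4 was 0.14 without 5xFAD/BAC-TREM2 replicate 4.

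**Figure D4:**
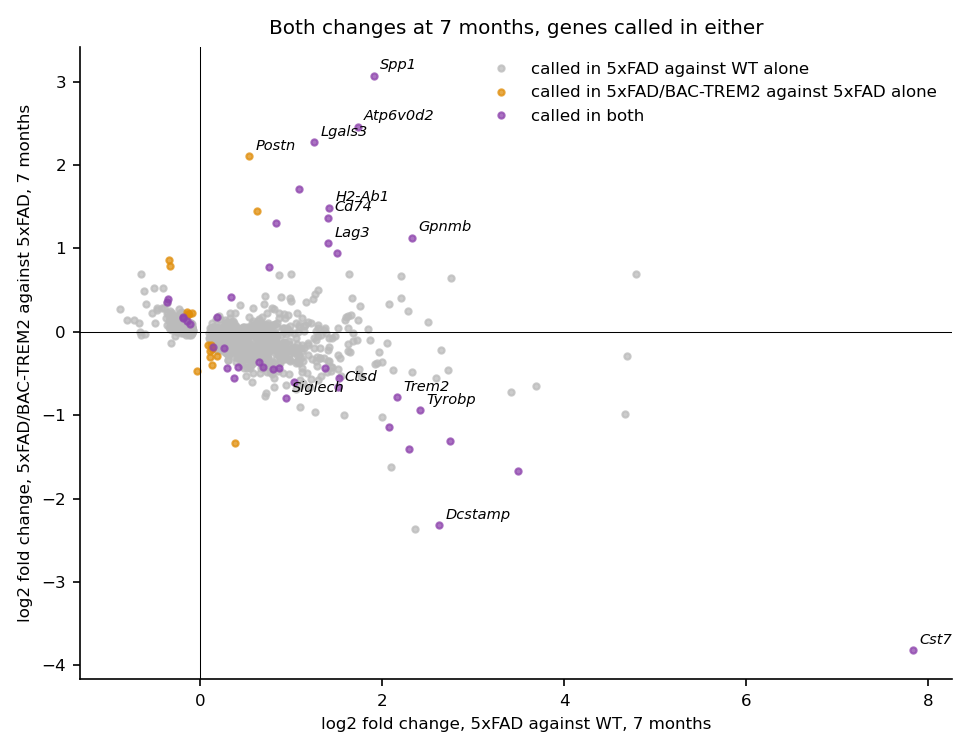
Log2 fold change of 5xFAD/BAC-TREM2 against 5xFAD (vertical axis) plotted against that of 5xFAD against WT (horizontal axis) at 7 months, with 1 point per gene called in either comparison, coloured by the comparison that called it. Spp1 (1.91 and 3.07) rose in both comparisons, and Cst7 (7.83 and -3.82) rose in the first and fell in the second; the 5xFAD libraries enter both axes with opposite signs.

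Set against BAC-TREM2 instead of WT, the 5xFAD transgenes gave the same 4 genes at 2 months, with Thy1 and App higher by 1.01 ± 0.04 and 0.24 ± 0.03 log2 (SE, n = 6 per group) and Mme lower by a log2 fold change of -0.65 ± 0.13. At 4 months Spp1 rose by 2.35 ± 0.24, Gpnmb by 1.62 ± 0.18, Ccl6 by 1.36 ± 0.22, Lyz2 by 1.32 ± 0.21, the inhibitory receptor gene Lag3 by 1.00 ± 0.17 and Itgax by 2.02 ± 0.28. Thy1, Cd68, Cd84 and Trem2 rose by 1.10 ± 0.04, 0.72 ± 0.15, 0.71 ± 0.17 and 0.68 ± 0.17, whereas Cst7 did not pass, at 1.21 ± 0.37 (adjusted p = 0.1). Mme, Cdh19, Gmps, Casp8ap2, Mphosph10, Kctd16, Vps13a and Nipbl were lower, with log2 fold changes from -0.71 to -0.25. At 7 months Spp1 and Gpnmb rose by 4.31 ± 0.24 and 3.53 ± 0.18, Lyz2 and Ccl6 by 3.19 ± 0.21 and 2.88 ± 0.22, H2-Ab1 and Cd74 by 2.84 ± 0.26 and 2.80 ± 0.27, and C4b and Gfap by 2.52 ± 0.21 and 2.37 ± 0.23. Trem2 rose by 1.40 ± 0.17. Tcap, Mme and Adcyap1, which encodes the neuropeptide PACAP, fell by 0.66 ± 0.17, 0.66 ± 0.13 and 0.59 ± 0.11, as did Dll4, Rpl22l1, Kifc5b, Jun and Scg2, by 0.58 ± 0.18, 0.52 ± 0.14, 0.51 ± 0.15, 0.43 ± 0.09 and 0.42 ± 0.10.

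The counts in 5xFAD/BAC-TREM2 against BAC-TREM2 were 3 higher and 1 lower, 46 higher and 30 lower, and 536 higher and 109 lower at 2, 4 and 7 months. With median-of-ratios size factors the split at 4 months was 30 higher and 38 lower. Voom gave 43 genes at 4 months and ended the call on Trem2 (adjusted p = 0.12), and the 24 libraries of 4 months gave 23. Without the BAC-TREM2 replicates 4 and 5 of 7 months, chosen as an alternative after the data were seen, the count at 7 months was 428, and Dll4, Kifc5b and Scg2 had adjusted p = 0.13, 0.057 and 0.16.

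Whether BAC-TREM2 changed the 5xFAD effect was tested as an interaction. At 4 months 5 genes passed, with the 5xFAD effect smaller on Cst7 (-5.34 ± 0.53 log2, SE), Ccl6 (-1.75 ± 0.31) and Tyrobp (-1.24 ± 0.25) and larger on Spp1 (1.70 ± 0.34) and Gpnmb (1.21 ± 0.25). At 7 months 13 passed, with Spp1 at 2.40 ± 0.34, Gpnmb at 1.20 ± 0.25 and the actin regulator gene Wasf3 at 0.21 ± 0.05 among the positive ones. Cst7 (-3.67 ± 0.53), Siglech (-0.82 ± 0.15), Ctsd (-0.68 ± 0.15), Unc13b (-0.39 ± 0.09) and Emc3 (-0.24 ± 0.05) were negative. The MHC class II list had a median of 1.23 at 7 months, with 0 of 6 genes called and 5 higher adjusted over the list alone (adjusted p = 0.052 with an estimated correlation). For homeostatic genes the medians were -0.34 and -0.31 at 4 and 7 months (0 and 1 called, 9 and 7 lower over the list alone; adjusted p = 0.064 and 0.11 with an estimated correlation).

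Limma called 0 genes for the interaction at 2 months (488 at an unadjusted p under 0.05; 0 by voom), 2 positive and 3 negative at 4 months, and 6 positive and 7 negative at 7 months (8 and 5 with median-of-ratios size factors). Voom left 2 genes at 4 months, where Spp1, Gpnmb and Tyrobp had adjusted p = 0.47, 0.47 and 0.37. At 7 months it left 3, and it ended the calls on Cst7, Gpnmb, Wasf3, Ctsd, Unc13b and Emc3 (adjusted p = 0.11, 0.081, 0.081, 0.077, 0.06 and 0.081). Preset correlations gave 3, 13 and 10 lists at 2, 4 and 7 months, and estimated ones 0.

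The genes that BAC-TREM2 moved in 5xFAD mice were compared with those that 5xFAD itself had moved. At 4 months 26 genes, Tyrobp, Trem2, Cst7 and Ccl6 among them, rose in 5xFAD against WT and fell in 5xFAD/BAC-TREM2 against 5xFAD, and 0 moved the same way in both. At 7 months 28 moved in opposite directions, of which 22 rose in 5xFAD and then fell with BAC-TREM2, and 13, Spp1, Gpnmb, Cd74 and H2-Ab1 among them, rose in both. If the calls were independent, 1.68 opposite and 0.82 same-direction genes would be expected at 4 months and 2.51 and 2.34 at 7 months. The 5xFAD libraries enter both comparisons, which by itself favours opposite signs, and the correlation of fold changes across genes was -0.59 and -0.42 against -0.49 and -0.50 in 50 simulations with no effect, in which the mean number of opposite genes was 0. Those simulations left out the 5xFAD effect as well. Their 0 therefore cannot tell how many opposite genes the shared libraries alone would give. When the 6 libraries were split 3 against 3 between the comparisons, the 20 splits had medians of 5.5 opposite genes (1 to 23) and 0 of the same direction (0 to 17) at 4 months, and 12 (3 to 72) and 7.5 (5 to 14) at 7 months. The correlation in the splits was -0.19 and -0.08; genes are not independent replicates.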

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

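The comparisons of the 5xFAD effect between ages, sexes and BAC-TREM2 states, and the count of other splits for each, were planned before the data were examined, while the tests on the chromosome 11 block, Mme and the microglial genes were chosen after those results were seen. The 5xFAD effect differed with BAC-TREM2 in 5 genes at 4 months and 13 at 7 months, which brought these counts here because limma tests the difference itself. At 4 months 4 of 100 splits of the samples gave as many genes and at 7 months 3 of 100, with 382 and 16 genes in the highest of the other splits. Both lie just under the limit of 5 of 100, with no adjustment over the comparisons, so chance is not firmly excluded. The splits for BAC-TREM2, age and sex shuffled that label separately in mice with and without 5xFAD. They thus test for any effect of the label, not for a difference of effects alone. Between ages the 5xFAD effect differed in 132 genes from 2 to 4 months, 1 gene from 4 to 7 months and 442 genes from 2 to 7 months. For the first and the last, 1 and 2 of 100 splits gave as many genes (highest other 11 and 585). That argues against no effect of age at all, but these splits cannot tell whether the 5xFAD effect itself differed. For the 1 gene from 4 to 7 months chance cannot be excluded (11 of 100; highest other 164). Between females and males the effect differed in 1, 22 and 3 genes at 2, 4 and 7 months. For these chance cannot be excluded, since 11, 12 and 34 of 100 splits gave as many, with 8, 59 and 321 genes in the highest other. Some splits called 382, 164 or 321 genes, many times the real count, and what those splits separate was not tested.

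A library stood far from the other 5 of its group in 3 of the 69 groups of values checked, and chance alone gives about 1 in 20 groups. Gpnmb was 2.88 RPKM in 5xFAD/BAC-TREM2 replicate 1 of 4 months, with the next at 1.72. Cd74 was 90.3 RPKM and H2-Ab1 29.6 RPKM in 5xFAD/BAC-TREM2 replicate 2 of 7 months, with the next at 33.2 and 12.4. Both genes belong to the MHC class II list, so these are not separate events. Their calls at 7 months against 5xFAD held in each of the 12 fits without 1 library.

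In BAC-TREM2 replicates 4 and 5 of 7 months, both females, 13 neighbouring genes from Camk2b to Ramp3 on chromosome 11 (5969644 to 6677475, mm10) had a median log2 deviation of -0.99, and the other 70 libraries lay between -0.08 and 0.07. A lower depth of both libraries is excluded by their 20.6 and 20 M reads against a median of 18.1 M in the others, and an effect of the BAC-TREM2 transgene by the 34 other carriers, the lowest of which was at -0.08. The value of -0.99 is consistent with the loss of 1 of 2 copies, which related animals could share: both sample names carry 1 first number, as does that of 5xFAD replicate 4 of 7 months, which is among the other 70, but DNA and kinship were not examined and the test was set from the same values. The scan found 1 further run past its limit, on chromosome 3 in 5xFAD replicate 1 of 7 months, with a median of 0.51. Leaving out both libraries moved the count in 5xFAD/BAC-TREM2 against BAC-TREM2 at 7 months from 645 to 428.

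Mme was lower in carriers of 5xFAD at every age, at 0.909 ± 0.19 RPKM in 36 carriers and 1.52 ± 0.19 in 36 other mice (SD). A response to pathology that grows with age is excluded as the whole cause: with both BAC-TREM2 states pooled the log2 effect was -0.65 ± 0.09 (SE) at 2 months and -0.73 ± 0.09 at 7 months, while the late disease-associated list had medians of 0.02 and 1.04. A local DNA difference inherited with the transgenes may lower it, since 3 of 7 neighbours within 1 Mb, Plch1, Gmps and Vmn2r1, had p under 0.05 at 2 months, and 0.2% of 554 windows of as many genes held as many. Plch1 and Gmps were lower in carriers, at -0.22 ± 0.06 and -0.09 ± 0.04, and Vmn2r1 was higher, at 0.62 ± 0.15. None of them passed limma's test over all genes at 2 months (lowest adjusted p = 0.16, for Vmn2r1). That window was chosen after the neighbours' values had been seen, and the strain of origin of this region was not examined. A direct effect of the transgenes that is complete by 2 months was not tested and stays open.

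In 5xFAD/BAC-TREM2 against 5xFAD some microglial genes fell while others rose: against the mean of the pan-microglial list, which itself differed by -0.31 and -0.21 at 4 and 7 months (two-sided exact permutation p = 0.095 and 0.31), Cst7 stood at -3.88 and -3.61 and Spp1 at 2.89 and 3.27 (adjusted p = 0.0044 for each, exact), 2 genes that were picked for their large changes. A lower share of microglia would lower all alike and so would not by itself give the rise of MHC class II. The mean of that fixed list rose by 1.27 against the pan-microglial list at 7 months (two-sided exact permutation test, p = 0.0022, adjusted p = 0.0044 over 10 comparisons, n = 6 per group). Those 10 include Cst7 and Spp1, picked for their large changes, which makes the adjusted p smaller than it would be without them. The MHC class II list was singled out after its rise was seen, so the outcome was known in advance. It has no bearing on the genes that fell. A lower dose of the 5xFAD transgenes is excluded by Thy1, at 0.06 on the log2 scale at 7 months. For the fall of homeostatic genes a lower share stays open, because against the pan-microglial list they differed by -0.02 at 4 months and -0.09 at 7 months (exact permutation p = 0.72 and 0.38). A change of microglial state was not tested and stays open.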

How the results depend on the processing

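Pseudocounts of 0.01 and 1, residual components, fits of 12 libraries, leaving out the chromosome 11 libraries, leaving out each library in turn and pooled BAC-TREM2 were chosen after the data were seen, and the other alternatives before. The planned DESeq2 and svaseq alternatives were not run. The deposited values are RPKM, and voom was the test fitted to the recovered reads, which also gave the size factors, the CPM values and the depths. The tallies here leave out the pooled BAC-TREM2 fits and the fits without 1 library. Over the other alternatives 221 counts stayed within 1.5 times the reported one and 76 moved. Of the values of named genes 4440 kept their side of the threshold, 29 passed it newly and 217 lost it; of list tests these were 1283, 9 and 100. None of the named genes that were called changed sign under the alternatives tallied. Fits of 24 and of 12 libraries ended the largest numbers of calls, 56 of 168 and 52 of 148, against 6 of 185 for size factors. Unless said otherwise the cause of a move was not tested.

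For 5xFAD against WT the 12 libraries alone called 2, 256 and 601 genes at 2, 4 and 7 months, and the 24 libraries 496 at 4 months. These fits have fewer samples to estimate the spread, and they also do not pool it with groups outside the comparison. Groups differ in spread, as Tyrobp at 4 months shows, at 47.2 ± 23 RPKM in 5xFAD and 14.3 ± 0.89 in WT (SD). Which of these ended calls was not tested. For BAC-TREM2 against WT, 1 gene was called at 4 months with 12 libraries, with 24 libraries, with a pseudocount of 0.01 and with residual components, and 1 at 2 months with residual components. For 5xFAD/BAC-TREM2 against 5xFAD, 12 libraries gave 10 and 26 genes at 4 and 7 months and 24 libraries 2 and 25, and at 7 months voom gave 99 and voom with the block 120. Against BAC-TREM2, 12 libraries gave 2 and 15 genes at 2 and 4 months. The 4-month count there was 23 with 24 libraries, 43 with voom, 19 with the block, 45 with no filter and 48 with no sex term, and the 7-month count was 428 without the chromosome 11 libraries.

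The interaction at 4 months gave 2 genes with voom and with the block, 3 with 24 libraries and 3 with no sex term. At 7 months it gave 3 with voom, with the block and with a pseudocount of 0.01, 6 with 24 libraries, 7 with a mean of at least 1 CPM and 22 with a pseudocount of 1. The change from 4 to 7 months gave 2 genes with size factors and without the chromosome 11 libraries, 3 with voom, with the block and with at least 1 CPM, 5 with no filter and 11 with a pseudocount of 1. For sex at 2 months the count was 0 with voom, with the block, with 24 libraries, with no filter, with at least 1 CPM, with a pseudocount of 1, with residual components and without the chromosome 11 libraries. At 4 months it was 12 with voom and 0 with 24 libraries, and at 7 months 0 with 24 libraries and 21 with a pseudocount of 1. Residual components gave 1847 genes for 5xFAD at 4 months, 89 and 222 for 5xFAD/BAC-TREM2 against 5xFAD at 4 and 7 months, 553 against BAC-TREM2 at 4 months, 14 and 165 for the interaction, and 509 and 67 for the age changes from 2 to 4 and 4 to 7 months. These components were taken from the residuals of the same model, so they remove residual spread by construction, and the counts are no independent evidence; the sex counts were 17 and 2 at 4 and 7 months.

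Leaving out 1 library gave ranges of 468 to 1675 and 835 to 1644 for 5xFAD against WT at 4 and 7 months, 15 to 64 and 30 to 168 for 5xFAD/BAC-TREM2 against 5xFAD, and 4 to 40 and 0 to 29 for sex. Of the 12 fits behind each range, 7, 1, 8, 5, 8 and 3, in that order, moved the count by more than 1.5 times. With an estimated correlation the number of lists past the threshold was 0 and 9 for 5xFAD at 2 and 4 months, 0 at each age for BAC-TREM2, 0, 1 and 2 for 5xFAD/BAC-TREM2 against 5xFAD, and 0 at each age for the interaction. Size factors left 1 list for the interaction at 2 months. With the 5xFAD libraries split 3 against 3 the medians of opposite genes were 5.5 and 12 at 4 and 7 months and of same-direction genes 7.5 at 7 months, and voom gave 52 opposite genes at 7 months. At 13.1 to 22 M reads per library, values near 0 such as Cst7 and Itgax in WT rest on few reads, and their fold changes depend on the pseudocount.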

Other observations

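The pooling of BAC-TREM2 over ages was chosen after the result at single ages was seen, and the splits and lists were planned. Over the 3 ages together, Itgax and Spp1 were higher in BAC-TREM2 than in WT, by 0.97 ± 0.16 and 0.77 ± 0.14 on the log2 scale (SE, 18 mice per group; adjusted p = 0.0018 and 0.006 by limma). Itgax was 0.216 ± 0.12 RPKM against 0.0531 ± 0.03 and Spp1 4.29 ± 0.97 against 2.46 ± 0.55 (SD), with 17 of 18 BAC-TREM2 mice above the WT median for each. These were the 2 genes called, with 1109 at an unadjusted p under 0.05, 3 called without the chromosome 11 libraries and 0 by voom. As 5 of 100 splits within age called as many genes, with 2 in the highest other, chance cannot be excluded for the count, and the splits did not test these 2 genes by name. With the 2-month mice of 5xFAD/BAC-TREM2 against 5xFAD added, also chosen after, 2 genes were called again, Itgax at 1.00 ± 0.14 and Spp1 at 0.80 ± 0.12 (24 against 24; adjusted p = 1.5e-05 and 9.1e-05). Itgax lies near 0, so its fold depends on the pseudocount.

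For the comparisons of pairs of groups, read at 0.05 with no adjustment over the comparisons, chance can be excluded for 5xFAD against WT at 2, 4 and 7 months (1, 2 and 1 of 100 splits gave as many genes; real 4, 1009 and 1283; highest other 2, 1692 and 953). It can also be excluded at each age for 5xFAD/BAC-TREM2 against BAC-TREM2 (1 of 100 each; real 4, 76 and 645; highest other 3, 30 and 488). For 5xFAD/BAC-TREM2 against 5xFAD both ages lay at the edge of the limit of 5 of 100, so chance is not firmly excluded for either. The values were 5 of 100 at 4 months (real 38, highest other 62) and 4 of 100 at 7 months (real 58, highest other 130). BAC-TREM2 against WT called 0 genes at each age, 5xFAD/BAC-TREM2 against 5xFAD 0 at 2 months and the interaction 0 at 2 months, so all 100 splits gave as many. In the BAC-TREM2 comparisons the highest other splits called 23, 1342 and 85 genes at 2, 4 and 7 months, and in the last pair 1 and 1. By limma 935, 490, 944, 590 and 488 genes had an unadjusted p under 0.05 in these 5 comparisons, and voom called 0 in each. What the splits with many calls separate was not tested. At 4 months reads on Rn45s made up 0.19% to 0.21% in BAC-TREM2 and WT replicates 1 to 3 and in 5xFAD replicates 1 and 2, both males. The other libraries of that age, every 5xFAD/BAC-TREM2 library among them, had 0.22% to 0.29%. Genotype and sex at 4 months are thus partly confounded with this difference, which no fit held as a term. This limit applies to the 4-month comparisons with 5xFAD/BAC-TREM2, the interaction and the sex differences.

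The first residual component held 4.3% of the residual variance and was led by immediate early genes, and the next held 3.6% and was led by choroid plexus genes. Immediate early genes averaged 5.03 ± 0.31 log2 RPKM in BAC-TREM2 mice of 7 months and 3.98 ± 0.44 in 5xFAD/BAC-TREM2 mice of 4 months (SD, n = 6 per group), the highest and lowest of the 12 groups. Choroid plexus genes were highest in 5xFAD mice of 4 months, at -0.09 ± 1.55, followed by 5xFAD mice of 7 months, at -0.11 ± 1.28.

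In 5xFAD against WT at 7 months the remaining lists did not pass camera with its preset correlation. Oligodendrocyte precursor genes had a median log2 fold change of 0.16, with 2 of 10 higher and 4 adjusted over the list alone (adjusted p = 0.075). Fibroblast and meninges, hippocampus, striatum, heat shock and leukocyte genes had medians of 0.22, 0.03, -0.08, 0.04 and 0.14 with 0 members called (adjusted p = 0.098, 0.46, 0.15, 0.85 and 0.57), and 1 hippocampus gene was higher adjusted over the list alone. Thalamus genes had 1 higher and 1 lower of 8 (1 and 1 adjusted over the list alone; adjusted p = 0.57), and oligodendrocyte genes 1 higher of 15 (1 adjusted over the list alone; adjusted p = 0.17). For the interaction at 7 months oligodendrocyte genes had a median of 0.26, with 0 of 15 called and 5 adjusted over the list alone (adjusted p = 6.1e-10, and adjusted p = 0.14 with an estimated correlation).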
